A study of Homo sapiens with 12 samples.

How the data were processed

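The data were 12 RNA sequencing libraries of 2 human cancer cell lines, 3 per line and treatment. Per the labels, NCI-H226 and ACHN cells seeded in 6-well plates received 100 nM SWTX-143 or DMSO overnight, and RNA was taken with RNeasy columns. Poly(A) libraries were read on a BGISEQ-500 as paired 100-base reads. The replicate numbers 1 to 3 recur in every group, and nothing in the sources used here says whether they stand for cultures, days or wells. The labels name no plate position, passage or sequencing lane, so no batch term was fitted.

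The deposited tables, 1 per line, held raw read counts per gene symbol as written by the authors. Every value was a whole number, column totals differed (9690980 to 11262663), and no scaling was seen in the values. Both tables listed the same 27064 symbols, of which 25667 had a RefSeq entry by name or synonym and 24646 a GENCODE transcript. The submitters' processing notes name FastQC, cutadapt, STAR 2.6.1d and the build hg19 (GRCh37). The counting program, its strand setting, its treatment of multi-mapping reads and the annotation release are not given in the sources used here. Without a strand setting, reads of genes that overlap another gene cannot be assigned to one of them. The report says where a gene named by rule overlaps another that was not far below it in level. Overlaps were not looked up for other genes, such as PPME1, SLC7A5 and TXNIP. The same holds for line markers and members of the added lists outside the rule. The reference annotation used here (GRCh38, GENCODE 29 and RefSeq) served only for symbols, synonyms, overlaps and transcript length and GC content, and no coordinate from the count tables was used.

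Read depth was even. Tested genes held 99.9% of counts, the 10 highest genes held 4.69% to 5.68%, and the TMM factors ran from 0.981 to 1.016. Over the 12 pairs of replicates in a group, the chi-square per degree of freedom of count differences was 1.36 to 3.42, so no library was a copy of another. CPM used TMM effective library sizes. The mitochondrially encoded genes were not analysed here, and neither were histone changes beyond the few histone genes tested.

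For each line, edgeR 4.0.16 in R 4.3.3 fitted SWTX-143 against DMSO. Genes passed filterByExpr, libraries were scaled by TMM, and robust quasi-likelihood F tests were adjusted by Benjamini-Hochberg over all tested genes of that line, with 0.05 as the limit for a call. A gene is written as risen, fallen or changed only if it passed. SE were derived from the fold change and its F statistic. The difference between lines was 1 contrast, the H226 effect minus the ACHN effect, in a joint fit of all 12 libraries with 14664 tested genes. The line and treatment groups, this test, its limit, the filter, the scaling, the 31 gene lists and the alternatives were all fixed before the data were examined. The refit of the difference on genes with at least 5 CPM in each line and the list test on the difference contrast were added afterwards. So were 4 further lists, of FOXO targets, tRNA synthetases, nucleotide synthesis genes and G1/S and replication genes. These 4 were adjusted among themselves within each line, and not together with the first lists.

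Gene lists were 31 sets written from general knowledge of the biology, none chosen on these samples. They covered 22 YAP/TEAD targets, other YAP-associated genes, Hippo components, S phase, G2 and mitosis, MAPK feedback, AP-1, actin and SRF, matrix, integrins, epithelial and mesenchymal states, p53, apoptosis, and ATF4. Cholesterol, lipid, glycolysis and hypoxia, oxidative phosphorylation, nucleolar, ribosomal protein, interferon, NF-kB, WNT and Notch, receptor kinase and tissue marker lists made up the rest. Lists with 3 or more tested genes were compared with all other tested genes by camera in limma 3.58.1 on voom weights, with the preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Of 30 lists tested in H226, 9 were called, and of 27 in ACHN, 14. The preset correlation is optimistic for small groups, so the adjusted p with estimated correlation is printed beside each called list. Under it no H226 list and 3 ACHN lists were called. Counts "adjusted over the list alone" used Benjamini-Hochberg within the list.

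Genes were named by a rule set in advance. It took the 10 largest rises and falls per line among called genes, the 22 targets, YAP1, WWTR1 and TEAD1 to TEAD4, up to 4 members of each list with the smallest p, and the 6 largest differences in each direction. Genes outside it are said to have been chosen after their values were seen, except line markers and members of the added lists, which carry no such remark. The ranking took called genes with a mean of at least 5 CPM and all 3 treated libraries on one side of all 3 DMSO libraries, 4539 in H226 and 2158 in ACHN. Clone-type names and pseudogenes were passed over.

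The tests were tried on simulated counts, drawn from negative binomial distributions with the mean levels of these libraries and the trend of dispersion over expression level. Genes with more spread than that trend were not represented. Far fewer genes were changed than were called in either line, so the counts that follow may not carry over to the real fits. Of 100 genes with a true change of 1 log2 unit, H226 returned 89 and ACHN 90, and at 0.5 units 65 and 79. False calls numbered 11 in H226 and 5 in ACHN. The difference test found 89 at 1 unit and 52 at 0.5, with 5 false. A gene reported as not called can thus have changed, even by 1 unit. DESeq2 1.42.0 served as an alternative test, and Python 3.11.15 with matplotlib 3.10.9 drew the plots.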

Results

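Poly(A) RNA was sequenced from the mesothelioma line NCI-H226 (H226) and the kidney cancer line ACHN. The submitters describe both lines as deficient in NF2, which encodes merlin, an upstream activator of the Hippo kinases that restrain the coactivators YAP and TAZ. Cells were held overnight in 100 nM SWTX-143, an irreversible inhibitor of the TEAD transcription factors that YAP and TAZ bind, or in DMSO. Each of the 4 groups held 3 libraries, and total counts ran from 9690980 to 11262663 in H226 and from 10113810 to 11206457 in ACHN. The labels do not say whether the 3 libraries of a group came from separate cultures. Every p-value here measures only the spread between these samples, which may be technical. Intervals written ± are SD for CPM, the counts scaled to library size, and SE for log2 fold changes, with n = 3 libraries per group throughout.

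The 2 lines carried the marker RNAs of their tissues. All 14 tested mesothelial markers were higher in H226 than in ACHN under DMSO, among them mesothelin (MSLN, 196 ± 2.00 against 0.777 ± 0.278 CPM) and calretinin (CALB2, 1020.5 ± 9.87 against 0.503 ± 0.277 CPM). Of 11 kidney markers, 8 were higher in ACHN, including the nephric transcription factor PAX8 (389 ± 9.78 against 1.19 ± 0.0539 CPM), while CDH6, AQP1 and MME were higher in H226. NF2 had no count in the 3 H226 DMSO libraries, where 3 pooled counts would have been 0.0933 CPM, and 1 count in the treated ones. ACHN did contain NF2 RNA, which fell from 118 ± 0.243 to 99.5 ± 5.13 CPM under the inhibitor (log2 fold change −0.25 ± 0.05, adjusted p = 5.53e-05). RNA level carries no information on whether the ACHN transcript encodes working merlin. Each line came as its own deposited table, so a difference between DMSO groups combines the line with anything that differed in its handling.

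In H226, the best-known YAP/TEAD target genes fell. CTGF (CCN2), a secreted matricellular protein and the most used readout of YAP activity, fell 5.78-fold, from 76.1 ± 7.11 to 13.2 ± 1.18 CPM (log2 fold change −2.53 ± 0.08, adjusted p = 1.83e-29). Its relative CYR61 (CCN1) fell from 888 ± 33.1 to 333 ± 6.49 CPM (−1.41 ± 0.04, adjusted p = 4.2e-35), and the nuclear ankyrin-repeat protein ANKRD1 from 12.5 ± 1.41 to 2.94 ± 0.207 CPM (−2.09 ± 0.15, adjusted p = 4.66e-17). Of 22 YAP/TEAD target genes listed without reference to these samples, 16 were lower and 0 higher, or 17 and 0 adjusted over the list alone, with a median log2 fold change of −0.59. Competitive gene-set testing placed the list below the other tested genes (adjusted p = 8.54e-14). With the correlation between its members estimated from the 6 libraries rather than preset, the adjusted p was 0.0583.

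The remaining falls in that list reached across its functions. The coagulation initiator tissue factor (F3) fell from 174 ± 2.71 to 54.6 ± 5.45 CPM (−1.67 ± 0.05), as did the growth-factor carrier IGFBP3 (−1.15 ± 0.04) and FJX1 (−1.03 ± 0.08), a relative of the polarity regulator four-jointed. The pathway's own brakes fell too: AMOTL2 (−0.83 ± 0.04), which holds YAP at junctions, and the Hippo kinase LATS2 (−0.77 ± 0.05). Other members called lower were NUAK2 (−0.82 ± 0.07), GADD45A (−0.61 ± 0.06), CCDC80 (−0.57 ± 0.04), CRIM1 (−0.45 ± 0.04), the receptor kinase AXL (−0.31 ± 0.04), ARHGEF17 (−0.22 ± 0.05), the ectonucleotidase NT5E (−0.21 ± 0.06) and FOXF2 (−0.25 ± 0.11, adjusted p = 0.0486). The cytokine TGFB2 was not called, its estimate large but uneven (−0.89 ± 0.39, adjusted p = 0.0639). ASAP1, DOCK5, MYOF, PTPN14 and RBMS3 were not called either, with log2 fold changes of 0.05, −0.06, −0.02, −0.14 and −0.12. DOCK5 and PTPN14 have long transcripts, and the treated H226 libraries differed in long transcripts, with a median for those over 12000 bases of 0.10 in replicate 3 against −0.06 and −0.11 in replicates 1 and 2.

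**Figure D1:**
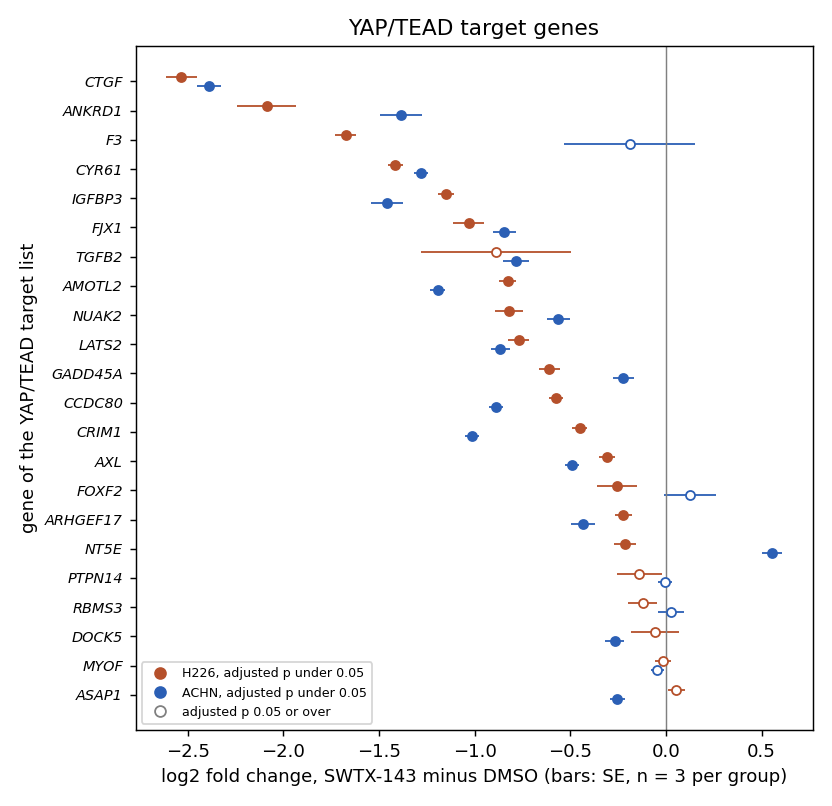
Log2 fold change (SWTX-143 over DMSO) with SE for 22 YAP/TEAD target genes in H226 and ACHN, n = 3 libraries per group. Filled points had an adjusted p under 0.05.

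Across the H226 transcriptome, the largest falls after CTGF were in the matrix glycoprotein THBS1 (−2.11 ± 0.15), ANKRD1, the potassium channel KCND3 (−2.02 ± 0.08), the natriuretic peptide NPPB (−1.99 ± 0.05, 185 ± 10.6 to 46.6 ± 1.84 CPM), the vitamin D hydroxylase CYP24A1 (−1.97 ± 0.05), the vasoactive peptide ADM (−1.83 ± 0.05), C1orf198 (−1.79 ± 0.06), the keratin KRT4 (−1.73 ± 0.14) and the activin subunit INHBA (−1.72 ± 0.06). The largest rises were in the mucin MUC16, the Kelch-family gene KLHL4 (1.98 ± 0.13), the muscle-atrophy ubiquitin ligase FBXO32 (1.94 ± 0.09, 11.6 ± 2.03 to 44.2 ± 1.66 CPM), MYH15 (1.80 ± 0.15), the amino-acid transporter SLC7A8 (1.73 ± 0.08) and NDRG4 (1.73 ± 0.08). AQP1 (1.71 ± 0.13), the sterol exporter ABCG1 (1.63 ± 0.19), the mTORC1 inhibitor SESN3 (1.58 ± 0.18) and the cytokine receptor IL22RA1 (1.52 ± 0.18) completed the 10 largest. MUC16 was the least even of these, from 4.62 ± 2.11 to 18.7 ± 6.85 CPM (2.01 ± 0.48, adjusted p = 0.0326), and its transcript is among the longest. In all, 5486 of 13484 tested genes changed (40.7%), 2919 lower and 2567 higher. That split depends on the scaling, with 2324 lower and 3283 higher under upper-quartile scaling and 2419 and 3110 under library size alone. Of the called genes, 123 were lower and 219 higher by more than 2-fold, and the median absolute log2 fold change was 0.35. Many of the 5486 changes were therefore small, and at a biological coefficient of variation of 3.98% the fit resolved shifts of that size.

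S-phase genes fell almost as a block in H226. UHRF1, which carries DNA methylation through replication, fell from 55.4 ± 0.666 to 23.6 ± 0.800 CPM (−1.23 ± 0.07, adjusted p = 3.45e-22), and the origin-licensing factor CDC6 from 81.3 ± 3.53 to 39.8 ± 1.35 CPM (−1.03 ± 0.06). The replicative helicase subunits MCM2 (−0.81 ± 0.05) and MCM4 (−0.69 ± 0.05) fell with them. Of 43 S-phase genes, 42 were lower and 0 higher (43 and 0 adjusted over the list alone), with a median of −0.59 and a list test of adjusted p = 1.17e-23, or 0.0558 with estimated correlation. Genes of G2 and mitosis fell less often: 17 lower and 1 higher of 50 (the same adjusted over the list alone), with a median of −0.10 (adjusted p = 0.00408; estimated correlation 0.280). The cytokinesis scaffold ANLN (−0.55 ± 0.04), TMPO (−0.44 ± 0.04), the mitotic kinesin KIF23 (−0.42 ± 0.04) and RANGAP1 (−0.48 ± 0.05) carried the smallest p-values there. MCM2, ANLN and TMPO each overlap another gene in the reference annotation (TPRA1, KIAA0895 and the TMPO antisense RNA), whose reads the counts cannot separate. RNA per cell phase was not measured, so lower S-phase RNA does not show whether fewer cells were in S phase or each transcribed these genes less.

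Nucleolar ribosome-biogenesis genes also fell in H226. The nucleolar helicase DDX21 fell from 300.0 ± 7.60 to 171 ± 5.34 CPM (−0.81 ± 0.04), and NOLC1 (−0.76 ± 0.04), the pseudouridine synthase DKC1 (−0.78 ± 0.05) and the spermidine synthase SRM (−0.70 ± 0.05) fell by similar amounts. Of 30 nucleolar and MYC-responsive genes, 26 were lower and 0 higher, the same adjusted over the list alone, with a median of −0.46 (adjusted p = 1.87e-17; estimated correlation 0.0535). MYC itself fell from 116 ± 4.68 to 85.2 ± 3.05 CPM (−0.45 ± 0.05). Cytosolic ribosomal proteins showed no such shift: RPL35 (−0.13 ± 0.04) and RPL27 (−0.11 ± 0.05) were called lower, 1 of them over the list alone, and the median of 33 genes was −0.02 (adjusted p = 0.637). Reads from ribosomal protein genes can also align to their many processed pseudogenes, so single genes of this family carry that uncertainty.

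Most interferon-stimulated genes rose in H226. The antiviral effector IFIT1 rose from 23.5 ± 1.41 to 37.0 ± 1.95 CPM (0.66 ± 0.08), and OASL (0.92 ± 0.14), IFI44 (0.63 ± 0.09) and the transcription factor IRF9 (0.51 ± 0.06) rose with it. Of 29 genes, 22 were higher and 1 lower (24 and 1 adjusted over the list alone), with a median of 0.41 and adjusted p = 5.56e-07, or 0.188 with estimated correlation. NF-kB and cytokine genes were mixed, with 8 higher and 4 lower of 21, the same adjusted over the list alone (adjusted p = 0.151). TNFAIP2 (0.71 ± 0.04), the mitochondrial superoxide dismutase SOD2 (0.53 ± 0.04) and CSF1 (0.55 ± 0.05) rose, while the adhesion molecule ICAM1 fell (−0.32 ± 0.04). SOD2 overlaps ACAT2 and WTAP.

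Part of the cytoskeletal list fell in H226, and part of the mesothelial and mesenchymal lists rose. Among 29 actin and SRF target genes, 13 were lower and 3 higher, the same adjusted over the list alone, led by TPM1 (−0.73 ± 0.04), FHL2 (−0.84 ± 0.05), LIMA1 (−0.60 ± 0.04) and the actin crosslinker ACTN1 (−0.50 ± 0.04). The median was only −0.06 (adjusted p = 0.0101; estimated correlation 0.462). Mesothelial markers had 8 higher and 3 lower of 15, again the same over the list alone, with a median of 0.18 (adjusted p = 0.0107; estimated correlation 0.188). The lectin ITLN1 (1.17 ± 0.08), LRRN4 (0.40 ± 0.04) and TBX18 (0.38 ± 0.05) rose, and CPA4 fell (−0.31 ± 0.04). Mesenchymal and TGF-beta genes had 10 higher and 2 lower of 21 (12 and 3 adjusted over the list alone), with a median of 0.23 (adjusted p = 0.0134; estimated correlation 0.188). ID1 (0.47 ± 0.04) and ID2 (0.45 ± 0.05), inhibitors of differentiation factors, rose in that list, against falls in INHBA and the receptor TGFBR1 (−0.73 ± 0.07).

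Further YAP-linked genes fell in H226, while the Hippo components divided. Of 38 other YAP-associated genes, 24 were lower and 4 higher, the same over the list alone, with a median of −0.28 (adjusted p = 7.86e-09; estimated correlation 0.0535). NPPB, CDC42EP3 (−0.93 ± 0.06), FGF2 (−0.75 ± 0.04), which overlaps NUDT6, and WWC2 (−0.70 ± 0.05) had the smallest p-values. Among the drug's direct targets, TEAD4 (−0.69 ± 0.06), TEAD3 (−0.39 ± 0.08) and TEAD1 (−0.36 ± 0.04) fell, while TEAD2 rose (0.39 ± 0.13). The coactivator genes YAP1 (0.13 ± 0.04) and WWTR1 (0.36 ± 0.06), the latter encoding TAZ, rose. The Hippo list of 32 genes, with DLG1 (−0.41 ± 0.04) and STRN4 (−0.34 ± 0.05) among those falling, had 12 lower and 5 higher (13 and 6 adjusted over the list alone; adjusted p = 0.166).

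The other H226 lists were not called as lists, although single members moved. In what follows the numbers in brackets are counts adjusted over the list alone. MAPK feedback genes had 4 (5) higher and 8 (8) lower of 21, with falls in the cyclin CCND1 (−0.56 ± 0.04), LIF (−0.73 ± 0.05), IER3 (−0.88 ± 0.08) and MYC (adjusted p = 0.209). AP-1 and immediate-early genes had 8 (8) higher and 4 (4) lower of 18, with JUN down from 171 ± 12.9 to 85.7 ± 2.51 CPM (−0.998 ± 0.05), DUSP1 down (−0.35 ± 0.04) and KLF10 (0.62 ± 0.06) and KLF2 (0.59 ± 0.07) up (adjusted p = 0.193). Collagen and matrix genes had 10 (11) higher and 4 (4) lower of 29, with LOX (0.29 ± 0.04), BGN (0.34 ± 0.05) and COL6A1 (0.26 ± 0.04) up and LOXL2 (−0.26 ± 0.04) down (adjusted p = 0.221). Integrin and adhesion genes had 10 (10) higher and 3 (3) lower of 32, with rises in ITGB8 (1.30 ± 0.09), ITGB4 (0.49 ± 0.04), CDH11 (0.50 ± 0.04) and L1CAM (0.46 ± 0.04) and adjusted p = 0.0555. Epithelial genes had 4 (4) higher and 6 (6) lower of 18, a negative median and a positive mean, with PKP2 (−0.88 ± 0.04), OCLN (−0.61 ± 0.07) and ESRP2 (−0.53 ± 0.06, overlapping NFATC3) down and KRT19 up (0.51 ± 0.04) (adjusted p = 0.637). WNT and Notch genes had 2 (2) higher and 2 (2) lower of 15, with DKK1 (−0.56 ± 0.08) and HES4 (−0.63 ± 0.13) down and NOTUM (0.92 ± 0.16) and AXIN2 (0.52 ± 0.11) up (adjusted p = 0.541). Receptor tyrosine kinases and ligands had 5 (5) higher and 6 (7) lower of 21, with FGF1 (−1.59 ± 0.29), ERBB3 (−1.15 ± 0.05) and NRG1 (−1.13 ± 0.18) down and GAS1 up (0.54 ± 0.09) (adjusted p = 0.552).

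Stress and metabolic lists in H226 were likewise not called. p53 targets had 11 (13) higher and 4 (5) lower of 24, with TP53INP1 (0.99 ± 0.09) and GDF15 (0.71 ± 0.07) up and PLK2 (−0.94 ± 0.04) and AEN (−0.57 ± 0.06) down (adjusted p = 0.166). BCL2-family and apoptosis genes had 4 (4) higher and 1 (1) lower of 13, including rises in the pro-death BCL2L11 (1.03 ± 0.09, overlapping MIR4435-2HG) and in BIRC3 (0.87 ± 0.07) and BIRC2 (0.21 ± 0.07), with BCL2L1, which overlaps ABALON, lower (−0.19 ± 0.05) (adjusted p = 0.166). ATF4 and unfolded-protein genes had 9 (10) higher and 5 (5) lower of 25: DDIT4 (1.40 ± 0.06), ERN1 (0.67 ± 0.08) and CEBPB (0.40 ± 0.05, overlapping its antisense RNA) rose and SLC3A2 fell (−0.54 ± 0.05) (adjusted p = 0.0983). Cholesterol genes had 6 (6) higher and 12 (12) lower of 27, with HMGCS1 (−0.31 ± 0.05) down but SREBF1 (0.38 ± 0.05) and TM7SF2 (0.42 ± 0.07, overlapping VPS51) up (adjusted p = 0.221). Glycolysis and hypoxia genes had 6 (7) higher and 10 (10) lower of 30, with ADM and the glucose transporters SLC2A3 (−1.22 ± 0.13) and SLC2A1 (−0.46 ± 0.06) down and CA9 up (0.54 ± 0.07) (adjusted p = 0.221). Lipid and PPAR genes had 3 (4) higher and 2 (2) lower of 11, with CPT1A (0.37 ± 0.07) and ACADVL (0.12 ± 0.04, overlapping DLG4) up and PPARD (−0.23 ± 0.06) and ACADM (−0.20 ± 0.07) down (adjusted p = 0.298). Oxidative phosphorylation had 2 (1) higher and 5 (4) lower of 32, with small falls in UQCRFS1 (−0.25 ± 0.05), NDUFS1 (−0.23 ± 0.07, overlapping EEF1B2), CYC1 (−0.20 ± 0.05) and SDHB (−0.18 ± 0.05) (adjusted p = 0.637). Marker sets for cell identity and library type followed. Kidney genes had 2 (2) higher and 1 (1) lower of 6, with AQP1 and LHX1 (0.88 ± 0.12) up and CDH6 down (−0.41 ± 0.05) (adjusted p = 0.277). Immune genes had 1 (3) higher and 0 (0) lower of 3, with CD68 up (0.32 ± 0.12) (adjusted p = 0.228), and endothelial genes had 0 (0) higher and 1 (1) lower of 3, with KDR down (−0.52 ± 0.05) (adjusted p = 0.358). Replication-dependent histones had 0 (0) higher and 0 (0) lower of 4 (adjusted p = 0.654).

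**Figure D2:**
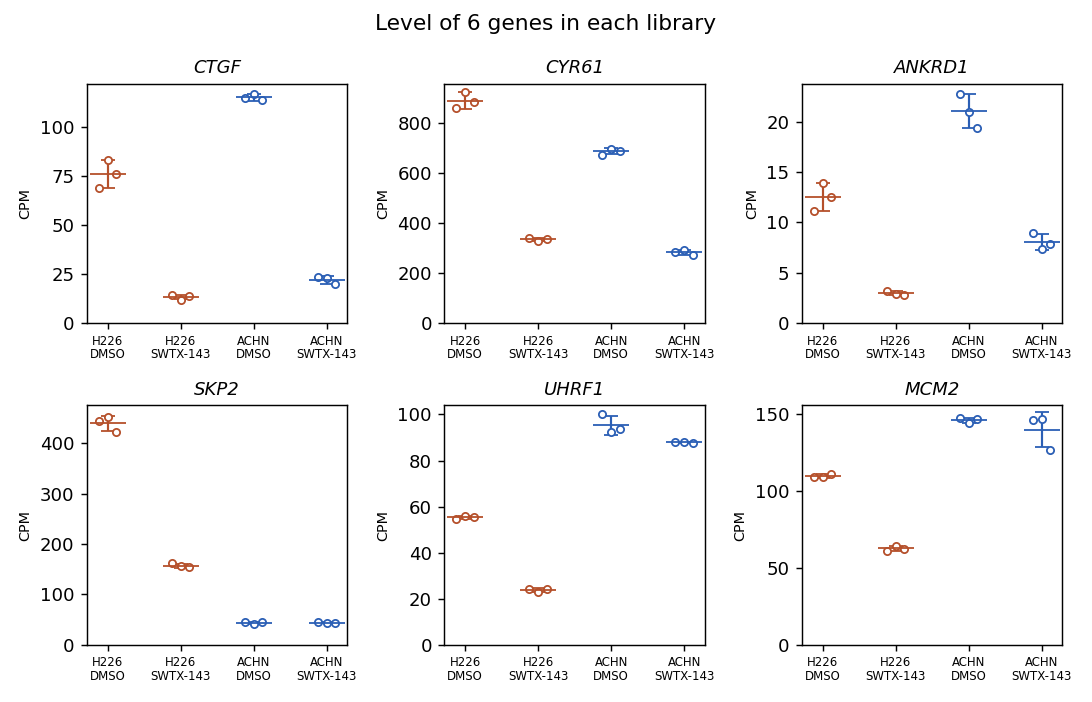
CPM of CTGF, CYR61, ANKRD1, SKP2, UHRF1 and MCM2 in each library of both lines. Bars are means and error bars SD of 3 libraries.

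In ACHN, most of the YAP/TEAD targets fell as well. CTGF fell 5.23-fold, from 115 ± 1.68 to 22.02 ± 2.09 CPM (−2.39 ± 0.06, adjusted p = 4.77e-35), CYR61 from 685 ± 12.2 to 282 ± 10.9 CPM (−1.28 ± 0.04) and ANKRD1 from 21.1 ± 1.71 to 8.05 ± 0.807 CPM (−1.38 ± 0.11). Of the 22 targets, 16 were lower and 1 higher, the same adjusted over the list alone, with a median of −0.53 (adjusted p = 8.94e-27; estimated correlation 0.00890). IGFBP3 fell more than CYR61 and ANKRD1 (−1.46 ± 0.08), and AMOTL2 (−1.19 ± 0.04), CRIM1 (−1.01 ± 0.04), CCDC80 (−0.89 ± 0.04), LATS2 (−0.87 ± 0.05), FJX1 (−0.84 ± 0.06) and TGFB2 (−0.78 ± 0.07) followed. Falls were also called in NUAK2 (−0.56 ± 0.06), AXL (−0.49 ± 0.04), ARHGEF17 (−0.43 ± 0.06), DOCK5 (−0.27 ± 0.05), ASAP1 (−0.25 ± 0.04) and GADD45A (−0.22 ± 0.05). NT5E was the exception, rising from 82.3 ± 7.25 to 121 ± 6.07 CPM (0.55 ± 0.05, adjusted p = 3.99e-12). F3, FOXF2, MYOF, PTPN14 and RBMS3 were not called (−0.19, 0.13, −0.05, 0.00 and 0.03), and F3 was close to silent in this line at 1.35 ± 0.382 CPM.

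Outside that list, the largest ACHN falls were in the vasoconstrictor peptide EDN2 (−2.10 ± 0.08, 70.9 ± 6.83 to 16.5 ± 0.907 CPM), the neurotrophin NTF3 (−1.75 ± 0.13), the growth-factor receptor FGFR2 (−1.72 ± 0.06, 90.3 ± 1.19 to 27.5 ± 1.73 CPM), ANO2 (−1.67 ± 0.13), STC2 (−1.51 ± 0.15), ZBED2 (−1.499 ± 0.10) and SHISA9 (−1.43 ± 0.06). The largest rises were in the progenitor transcription factor SOX9 (1.60 ± 0.14), the adhesion molecule VCAM1 (1.46 ± 0.08, 19.6 ± 2.07 to 54.0 ± 2.73 CPM), the carbonic anhydrase CA12 (1.24 ± 0.16), the channels TRPM8 (1.01 ± 0.10) and KCNJ16 (1.00 ± 0.14), and TRIB1 (1.00 ± 0.11). The death ligand TNFSF10 (0.95 ± 0.10), METTL7A (0.93 ± 0.12), IRAK2 (0.88 ± 0.10) and PNRC1 (0.87 ± 0.09) followed. In all, 2401 of 13483 tested genes changed (17.8%), 1264 lower and 1137 higher, with a median absolute log2 fold change of 0.26. The split turned with the scaling, to 1028 lower and 1450 higher under upper-quartile scaling and 977 and 1537 under library size alone. Changes above 2-fold were rare, 50 lower and 24 higher, and the biological coefficient of variation was 3.23%.

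S-phase genes were not called lower as a list in ACHN. UHRF1 (−0.12 ± 0.05), MCM2 (−0.06 ± 0.05) and MCM4 (0.00 ± 0.04) were not called, and of 43 S-phase genes 3 were lower and 1 higher (2 and 0 adjusted over the list alone; median −0.01, adjusted p = 0.409). CDC6 (−0.14 ± 0.04), RAD51AP1 (−0.21 ± 0.05) and RRM2 (−0.12 ± 0.04) were the 3 lower, and CENPU, which overlaps PRIMPOL, was higher (0.17 ± 0.06). The calls of CDC6, RRM2 and CENPU were lost under some other settings (adjusted p up to 0.0707, 0.154 and 0.196). Some mitotic genes fell slightly, with 11 lower and 0 higher of 50, the same over the list alone (median −0.06, adjusted p = 0.000173; estimated correlation 0.151). CDC20 (−0.27 ± 0.04), ANLN (−0.26 ± 0.03), KIF23 (−0.26 ± 0.04) and CKAP5 (−0.18 ± 0.04) were among them. Most nucleolar genes fell, with a smaller median shift than in H226, 18 lower and 1 higher of 30 (20 and 1 adjusted over the list alone), with a median of −0.19 (adjusted p = 1.23e-09; estimated correlation 0.0483). UTP20 (−0.33 ± 0.04), DDX21 (−0.28 ± 0.04), NOLC1 (−0.23 ± 0.04) and nucleolin (NCL, −0.20 ± 0.03) led. Ribosomal proteins had 2 higher of 33, or 1 adjusted over the list alone, RPL27 (0.15 ± 0.04) and RPL4 (0.09 ± 0.03) (adjusted p = 0.366).

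Some interferon-stimulated and NF-kB genes rose in ACHN. IFIT2 (0.43 ± 0.10), OAS1 (0.32 ± 0.08), IRF1 (0.32 ± 0.08) and PARP9 (0.31 ± 0.07, overlapping DTX3L) rose, and of 24 interferon-stimulated genes 10 were higher and 0 lower (13 and 0 adjusted over the list alone; median 0.24, adjusted p = 5.39e-05; estimated correlation 0.0523). Among 18 NF-kB and cytokine genes 5 were higher and 1 lower (7 and 2 adjusted over the list alone; median 0.13, adjusted p = 0.00193; estimated correlation 0.0916). VCAM1, SOD2 (0.34 ± 0.04) and TNFAIP2 (0.30 ± 0.04) rose there, against a fall in IL6 (−1.27 ± 0.29). Mesenchymal genes had 7 higher and 0 lower of 16, the same over the list alone, with ID3 (0.52 ± 0.14), ID1 (0.46 ± 0.13), LTBP2 (0.26 ± 0.06) and TGFBR2 (0.23 ± 0.05) up (median 0.11, adjusted p = 0.0101; estimated correlation 0.139). Integrin and adhesion genes had 10 higher and 4 lower of 31 (10 and 5 adjusted over the list alone), with TNS1 (0.59 ± 0.06) and ITGB1 (0.19 ± 0.03) up and the caveolins CAV1 (−0.15 ± 0.03) and CAV2 (−0.20 ± 0.04) down (adjusted p = 0.0188; estimated correlation 0.203). Kidney markers had 3 higher and 0 lower of 8, the same over the list alone, with LHX1 (0.68 ± 0.09), CDH16 (0.53 ± 0.09) and GGT1 (0.32 ± 0.05) up (median 0.05, adjusted p = 0.0242; estimated correlation 0.348).

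**Figure D3:**
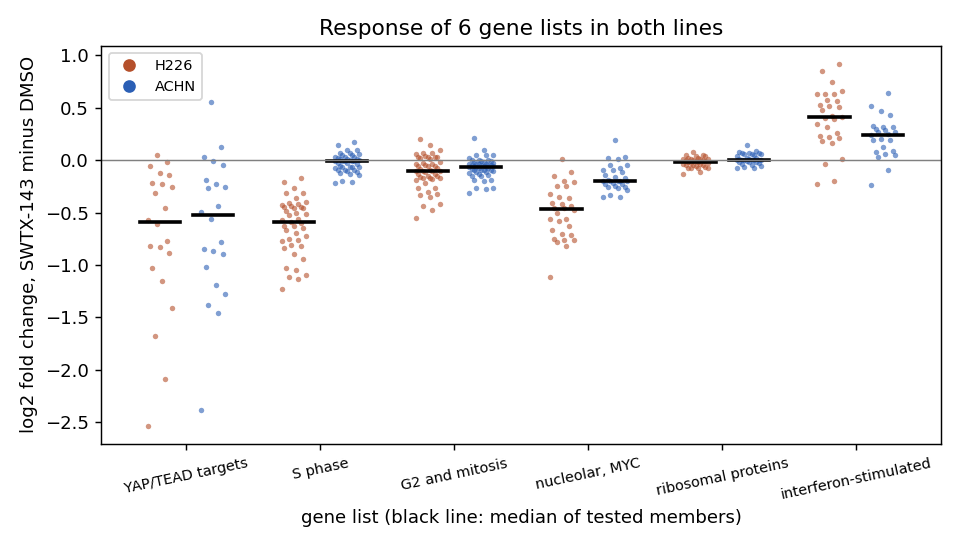
Log2 fold change of each tested member of 6 gene lists in H226 and ACHN, from 3 libraries per group. Black lines mark the median of each list.

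In several other ACHN lists, most of the called genes fell. The remaining YAP-associated genes had 22 lower and 1 higher of 35 (24 and 2 adjusted over the list alone; adjusted p = 3.28e-19; estimated correlation 0.00890), including AJUBA (−0.99 ± 0.05), FSTL1 (−0.74 ± 0.05), CDC42EP3 (−0.74 ± 0.05) and WWC1 (−0.55 ± 0.04). Hippo components had 10 lower and 2 higher of 34, the same over the list alone (adjusted p = 0.00313; estimated correlation 0.0916). TEAD1 (−0.51 ± 0.04), TEAD4 (−0.24 ± 0.05), WWTR1 (−0.15 ± 0.04), the polarity protein MPP5 (−0.35 ± 0.05) and the atypical cadherins FAT1 (−0.53 ± 0.04) and FAT4 (−0.53 ± 0.08) fell, YAP1 rose (0.20 ± 0.04), and TEAD2 (0.07) and TEAD3 (−0.09) were not called. Cholesterol genes had 9 lower and 0 higher of 28 (12 and 1 adjusted over the list alone), among them FASN (−0.36 ± 0.04) and ACACA (−0.19 ± 0.04) (median −0.11, adjusted p = 0.000258; estimated correlation 0.151). ATF4 and unfolded-protein genes had 9 lower and 2 higher of 25 (10 and 2 adjusted over the list alone), with VLDLR (−0.42 ± 0.05), SLC3A2 (−0.40 ± 0.05), HERPUD1 (−0.26 ± 0.05) and the chaperone HSPA5 (−0.25 ± 0.03) down (median −0.09, adjusted p = 0.00182; estimated correlation 0.267). Glycolysis and hypoxia genes had 7 lower and 1 higher of 28 (8 and 1 adjusted over the list alone), with ADM (−1.32 ± 0.15), HK2 (−0.51 ± 0.06), SLC2A1 (−0.49 ± 0.05) and PFKP (−0.20 ± 0.04) down (adjusted p = 0.0147; estimated correlation 0.612). Receptor kinases and ligands had 8 lower and 3 higher of 20 (8 and 6 adjusted over the list alone), with FGFR2, PDGFB (−0.58 ± 0.06), EGFR (−0.53 ± 0.04) and NRG1 (−0.43 ± 0.04) down (adjusted p = 0.0242; estimated correlation 0.331).

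The lists left in ACHN were not called. MAPK feedback genes had 5 (7) higher and 5 (6) lower of 23, with a positive median but a negative mean, and HBEGF (−0.71 ± 0.12), EPHA2 (−0.61 ± 0.04), LIF (−0.46 ± 0.04) and FOSL1 (−0.40 ± 0.04) down (adjusted p = 0.513). Collagen and matrix genes showed the same contrast of median and mean, with 9 (10) higher and 8 (8) lower of 25 and COL12A1 (−0.88 ± 0.07), SPARC (−0.63 ± 0.04), COL4A1 (−0.53 ± 0.04) and COL4A2 (−0.27 ± 0.03) down (adjusted p = 0.486). AP-1 genes had 3 (4) higher and 2 (3) lower of 19, with DUSP1 down (−0.87 ± 0.05) and JUNB (0.45 ± 0.09), KLF6 (0.28 ± 0.04) and BTG2 (0.25 ± 0.06) up (adjusted p = 0.513). Actin and SRF genes had 5 (6) higher and 10 (12) lower of 29, with FLNC (−0.37 ± 0.04), TPM1 (−0.23 ± 0.03) and ACTN1 (−0.22 ± 0.04) down (adjusted p = 0.112). Epithelial genes had 2 (3) higher and 4 (5) lower of 21, their median and mean again of opposite sign, with PKP2 (−0.75 ± 0.05) and the keratins KRT18 (−0.28 ± 0.03) and KRT8 (−0.25 ± 0.03), which overlap each other, down and KRT19 up (0.34 ± 0.04) (adjusted p = 0.380).

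Death, lipid and identity genes in ACHN completed the set. p53 targets had 3 (3) higher and 2 (3) lower of 25, with SESN2 (0.46 ± 0.06) and TP53INP1 (0.40 ± 0.07) up and XPC (−0.34 ± 0.04, overlapping LSM3) and PLK2 (−0.25 ± 0.03) down (adjusted p = 0.148). Apoptosis genes had 4 (4) higher and 4 (4) lower of 14, with BIRC3 (0.61 ± 0.06) and XIAP (0.31 ± 0.06) up and BCL2L1 (−0.35 ± 0.04) and CFLAR (−0.24 ± 0.04) down (adjusted p = 0.719). Lipid genes had 2 (2) higher and 1 (2) lower of 15, with ANGPTL4 (0.61 ± 0.10) and HADHB (0.15 ± 0.05) up and PPARD down (−0.38 ± 0.13) (adjusted p = 0.306). Oxidative phosphorylation had 0 (0) higher and 1 (1) lower of 32, the lower gene being SDHB (−0.21 ± 0.06) (adjusted p = 0.490). WNT and Notch genes had 1 (3) higher and 0 (1) lower of 10, with HES1 up (0.53 ± 0.11) (adjusted p = 0.391). Mesothelial markers had 1 (1) higher and 3 (3) lower of 6, with BNC1 (−0.81 ± 0.26), UPK3B (−0.51 ± 0.17) and LRRN4 (−0.26 ± 0.04) down and GATA6 up (0.79 ± 0.21) (adjusted p = 0.114). Immune markers had 2 tested genes, with CD68 up (0.42 ± 0.06), endothelial markers 2 and histones 1, neither with a call, so no list test was run on these.

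The 2 lines shared much of their response. Of 12333 genes tested in both, 731 fell in both and 536 rose in both, against 271 and 179 had the calls been independent (odds ratios 6.89 and 6.69). Under upper-quartile scaling 544 fell and 783 rose in both, and under library size alone 533 and 803. Only 122 were called in opposite directions, and the log2 fold changes of all 12333 genes correlated with Pearson r = 0.449 and Spearman r = 0.442. Shared falls included CTGF, CYR61, ANKRD1, IGFBP3, DDX21 and TEAD1, and shared rises included SOX9 (1.497 ± 0.33 in H226), PNRC1 (1.02 ± 0.06) and TRIB1 (0.35 ± 0.09). Of the ACHN calls, 83.0% had the same sign in H226. Both lines met the same compound under the same protocol, so an effect of the compound away from TEAD would be shared as well.

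Of genes outside the naming rule, 3 were chosen after their values in both lines were seen. The phosphatase methylesterase PPME1 fell in H226 (−1.65 ± 0.04) and ACHN (−1.17 ± 0.05), and so did the amino-acid transporter SLC7A5 (−1.45 ± 0.04 and −0.84 ± 0.04). TXNIP, an arrestin that limits glucose uptake, rose in both (0.98 ± 0.05 and 0.73 ± 0.04). Each of these 6 changes was called.

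**Figure D4:**
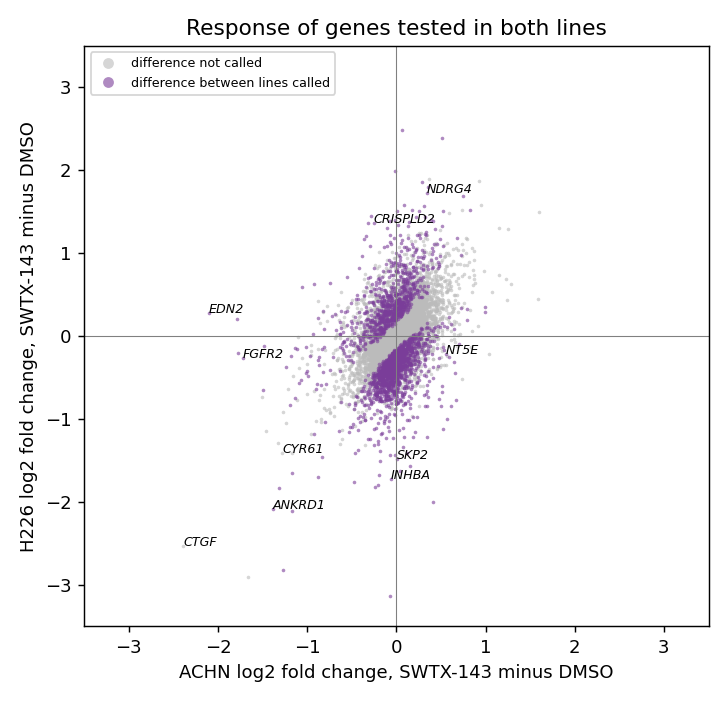
Log2 fold change in H226 against ACHN for 12333 genes tested in both lines, 3 libraries per group. Purple points had a called difference between the lines.

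S-phase genes had a more negative effect in H226 than in ACHN, the list difference with the smallest p-value. In the direct test of the H226 effect minus the ACHN effect, 39 of 43 S-phase genes had a more negative and 0 a more positive effect in H226 (median difference −0.57, adjusted p = 3.48e-39; estimated correlation 0.00509). UHRF1 differed by −1.12 ± 0.08, CDC6 by −0.89 ± 0.07, MCM2 by −0.76 ± 0.07 and MCM4 by −0.70 ± 0.06. Nucleolar genes followed, with 25 of 30 more negative (median difference −0.32, adjusted p = 3.68e-18; estimated correlation 0.00536). The YAP/TEAD targets as a list were not called different (median difference −0.13, adjusted p = 0.674). The list test itself leaned up, with 5 members more positive and 4 more negative in H226. CTGF was close to equal (−0.15 ± 0.11, adjusted p = 0.414). Of 14664 genes, 2286 had a called difference, 1423 more negative and 863 more positive in H226. The split shifted to 1179 and 1017 under RLE scaling, 1045 and 1159 under upper-quartile scaling, and 1267 and 962 under library size alone, so neither direction is a firm majority.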

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

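Of the tests in this part, the carry-over, low-expression, scaling, G2 and replication gene tests were chosen only after the result was seen, while the length and GC and label-split tests were written before their own outcome was known.

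The 2 lines answered the inhibitor differently in 2286 genes, and the S-phase list differed by a median of −0.57 log2 units, lower in H226. The H226 S-phase median was −0.54 (−0.64 to −0.43) under the scaling that brought it nearest 0. The scalings tried moved the median of all H226 genes only from −0.001 to 0.048, so they could not test a larger scaling error. Bracketed ranges after medians, list differences, Spearman r and the dispersion index, here and below, come from resampling genes. They leave out the spread between libraries and the correlation between members. Taking off the trend with transcript length and GC content left −0.52 (−0.62 to −0.43). The G2 list lay 0.49 (0.36 to 0.61) above the S-phase list, where an equal loss of cells from every cycling phase would have lowered both alike. These values argue against the scalings tried, that trend and such an equal loss as the source of the fall. A larger scaling error, or a loss uneven between phases, was not tested. A further list of G1/S and replication genes was lower in 26 of 28 (camera p = 1.09e-15, adjusted p with estimated correlation 0.020). It was written after the fall was seen and restates it without explaining it. Whether fewer cells were in S phase or each transcribed these genes less stays open, and phase fractions by flow cytometry in both lines at the same hour would separate the 2.

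Regrouping the libraries gave as many called differences as the true labels in 4 of 100 splits, counting the true one. The split with most, 5167, kept the true H226 groups and reversed the ACHN labels, which adds the effects of both lines. Those with 2686 and 2425 kept the true H226 groups and mixed the ACHN ones, so the H226 effect is still in them.

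Some differences came from genes almost silent in a line: SLPI, CDH11, ALDH1A2, CADM3, HSD3B1 and UCHL1 had 20, 7, 11, 6, 7 and 6 pooled counts in ACHN DMSO libraries and 0 in treated ones. Across 93 H226-rich genes, chosen as at least 1000 times lower in treated ACHN, ACHN DMSO counts tracked the H226 level (Spearman r = 0.678, 0.53 to 0.79). Treated ACHN counts of genes chosen likewise on the DMSO libraries gave 0.162. Those were 76 counts in 21 of 81 genes, against 313 in 59 of 93, so these values are not on equal terms. ACHN-rich genes chosen likewise gave 0.362 in H226 DMSO and 0.440 in treated H226, so tracking was not particular to ACHN DMSO libraries. Over 88 H226-rich genes at least 1000 times lower across all ACHN libraries, ACHN DMSO counts came to 54.3, 28.3 and 46.3 parts per 100000 of the H226 level. In the treated libraries they came to 12.7, 11.1 and 18.5, so a trace of H226 material in the ACHN DMSO libraries is a candidate explanation. The ratio of ACHN to H226 counts varied between genes with a dispersion index of 3.72 (1.90 to 5.64), a range too wide to judge low true expression in ACHN, so carry-over and expression that ended under the inhibitor cannot be told apart by it. Genotype calls at sites where the lines differ, from the reads of the ACHN DMSO libraries, would settle this.

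BDH1 had 7 pooled counts in H226 DMSO and 0 in treated libraries, and carry-over points the other way there. Over 74 ACHN-rich genes chosen likewise, H226 DMSO counts came to 22.6, 23.2 and 19.997 parts per 100000 of the ACHN level, against 26.2, 41.2 and 37.4 in treated H226.

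The other lists that differed were the nucleolar genes (−0.32), mesothelial markers (0.67, of which ACHN expressed few), ATF4 genes (0.13), matrix genes (0.15) and actin genes (−0.07). With estimated correlation their adjusted p was 0.00536, 0.0475, 0.141, 0.450 and 0.715. Only 6 of the 15 mesothelial markers passed the filter in ACHN alone, and their H226 list median was 0.18. Most of the differences behind 0.67 thus involve genes near the floor in ACHN. The trace counts of H226-rich genes described above could have moved this list, and the 2 were not separated. Among YAP/TEAD targets, ANKRD1 (−0.71), F3 (−1.49), NT5E (−0.77) and GADD45A (−0.39) had more negative effects in H226, and AMOTL2 (0.36), ASAP1 (0.30), AXL (0.18), CRIM1 (0.56) and CCDC80 (0.31) more positive ones. WWTR1 (0.51) and TEAD4 (−0.46) differed too.

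Among genes with at least 5 CPM in each line, chosen after their values were seen, the largest positive differences were in EDN2 (2.37), CRISPLD2 (1.62), FGFR2 (1.44), the integrin ITGB8 (1.41), NDRG4 (1.38) and TNFRSF19 (1.37). The largest negative ones were in the homeobox gene MSX1 (−1.73), DDX20 (−1.67), INHBA (−1.66), C1orf198 (−1.59), B3GNT7 (−1.58) and the ubiquitin ligase subunit SKP2 (−1.50), which fell from 439.9 ± 14.9 to 157 ± 3.87 CPM in H226 and was not called in ACHN, at 43.8 ± 1.88 and 43.9 ± 0.930 CPM in ACHN. Without that limit on expression, the rule gave RIMS2 (−3.07), MBOAT1 (−2.41), SEMA3E (−1.92), SYNPO2L (−1.83) and CDH6 (−1.76) besides the near-silent genes above. Of these, SYNPO2L (8 and 12 pooled counts) and CDH6 (7 and 19) were near-silent in ACHN DMSO and treated libraries and SEMA3E (28 and 5) in H226, and their calls were lost under some settings (adjusted p up to 0.406, 0.124 and 0.0785). UCHL1 and BDH1 also lost their called difference under some settings, with adjusted p up to 0.206 and 0.145.

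Of 243 named genes, 114 had a called difference, against 2286 of all 14664 tested. The naming rule picked many of them for large changes or small p in a line, which favours a higher share. Among the 243, 11 were called in opposite directions: CENPU, HERPUD1, KLF6, LOX, LRRN4, NT5E, RPL27, SREBF1, UPK3B, WWTR1 and XPC. Some of these calls did not last under other settings, with an adjusted p of up to 0.305 for RPL27 in H226 and up to 0.196 for CENPU, 0.150 for UPK3B and 0.0724 for WWTR1 in ACHN.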

How the results depend on the processing

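Of the settings in this part, the refit on genes with at least 5 CPM in each line and the list test on the difference were chosen only after the result was seen.

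No called gene or difference among those named reversed its direction, and no called list reversed the direction of its test. List medians near 0 did change sign with the scaling, among them the called ACHN glycolysis list (0.002 under library size), MAPK, epithelial, receptor kinase, ribosomal and oxidative phosphorylation lists in H226, and S-phase, epithelial and oxidative phosphorylation lists in ACHN. Over all alternatives, the 1.5-fold threshold and the replicate block included, 2301 of 2457 checks of named H226 genes gave the same outcome, called or not. Of the 137 lost calls, 85 came from the 1.5-fold threshold, and 19 calls were gained. In ACHN 2251 of 2423 checks gave the same outcome (161 lost, 102 of them by that threshold, and 11 gained), and for the difference 477 of 516 (39 lost, 9 by the threshold). For lists it was 299 of 328 in H226 and 268 of 297 in ACHN, lists not called in either setting included.

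Asking for a change beyond 1.5-fold left 331 genes in H226 (164 lower, 167 higher), 64 in ACHN (54 and 10), 72 differences (42 negative, 30 positive) and 22 genes shared by both lines, with 9 YAP/TEAD targets lower in each. DESeq2 called 3896 genes in H226 against 5486 in the main fit, 1473 in ACHN, 762 in both lines and 1571 differences against 2286. The refit on genes with at least 5 CPM called 2112 differences, 1063 positive and 1049 negative. The correlation between lines was 0.0740 with no filter, where genes of few counts add noise, and 0.510 with the strict one. Estimated correlation left 0 of 9 called lists in H226, 3 of 14 in ACHN and 3 of 6 for the difference, while fry called 22 in H226 and 18 in ACHN.

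Libraries of the same replicate number had residual correlations across treatment of −0.18, −0.20 and −0.06 in ACHN, which gives no sign of pairing. In H226 they were −0.06, 0.28 and 0.15. Pairs of unlike number were not compared, so pairing in H226 is not excluded. With replicate number as a block, 5744 H226 genes, 2146 ACHN genes, 2328 differences and 1188 shared genes were called, and no list call changed. PPARD, RRM2 and RPL4 lost their ACHN call in the block model.

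Leaving out 1 library at a time gave 4753 to 5365 called genes in H226, 1841 to 2174 in ACHN, 1780 to 2253 differences and r from 0.392 (without ACHN_SWTX143 replicate 3) to 0.455. The split of the differences is not stable: positive ones were the majority in 5 of 6 fits without an H226 library, for example without H226_DMSO replicate 2 (832 negative, 948 positive) and without H226_SWTX143 replicate 3 (971 and 1140). Between 15 and 17 YAP/TEAD targets were lower in H226, their members changing, and 16 in ACHN. MUC16 was lost in H226 without a filter (adjusted p = 0.0516) and in 5 of 6 fits with a library left out (0.0551 to 0.104), YAP1 without H226_DMSO replicate 3 (0.119) or H226_SWTX143 replicate 1 (0.0521), TEAD2 under DESeq2 (0.0837) and without H226_DMSO replicate 2 (0.0869) or H226_SWTX143 replicate 1 (0.0545), and FOXF2 under most settings (up to 0.214). Without H226_SWTX143 replicate 3, PTPN14 (0.00157) and DOCK5 (0.00053) were called lower and FOXF2 was lost (0.0968). TGFB2 gained a call as lower under limma-voom (0.0371), in the fit of all 12 libraries (0.0494) and without H226_SWTX143 replicate 2 (0.0181). In ACHN, WWTR1 was lost without ACHN_DMSO replicate 1 (0.0724), ID1 (0.135) and IRF1 (0.0617) without ACHN_DMSO replicate 3, and in the fit of all 12 libraries DOCK5 (0.173), FAT1 (0.0655) and FAT4 (0.0664) were lost. The ACHN glycolysis list was lost without ACHN_DMSO replicate 2 (0.0767) or ACHN_SWTX143 replicate 3 (0.0626) and under fry (0.149). The ACHN integrin list was lost without ACHN_SWTX143 replicate 2 (0.0552). The kidney list was lost without ACHN_DMSO replicate 1 (0.0551) or ACHN_SWTX143 replicate 3 (0.0626), and the receptor kinase list under the strict filter (0.0764). Gains in ACHN included the actin list without ACHN_DMSO replicate 1 (0.0399) and the mesothelial list under the strict filter (0.0472). The ACHN ribosomal protein list was gained under library-size scaling (0.0488), and the H226 ATF4 list without H226_SWTX143 replicate 3 (0.0338). The H226 integrin list was gained under RLE (0.0486), upper-quartile (0.0291) and library-size scaling (0.0294), the strict filter (0.0137) and 4 of 6 fits with a library left out (0.0173 to 0.0387), and CDH11 lost its difference without ACHN_DMSO replicate 1 (0.0561).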

Other observations

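Of the tests in this part, the NF-kB one was chosen only after the result was seen, the others before their own outcome was known. FOXO targets, which rise when AKT signalling falls, were higher in H226: 20 of 26 rose and 2 fell (median 0.35, camera p = 1.71e-06; adjusted p with estimated correlation 0.020). For the added lists, here and below, camera p is unadjusted, and estimated-correlation p is adjusted over the added lists alone. The latter cannot be ranked against the first lists. Before adjustment it was 0.00588 for FOXO targets and 0.0171 for nucleotide synthesis in H226. For the H226 S-phase and YAP/TEAD lists, not called with estimated correlation, it was 0.00558 and 0.00778. PIK3IP1 (1.505), C10orf10 (1.15), YPEL3 (1.09), KLHL24 (0.95) and TRIB2 (0.74) rose, and ERBB3 (−1.15) and CITED2 (−0.50) fell. In ACHN 9 of 23 rose and 3 fell (median 0.15, p = 0.0352; estimated correlation 0.31), with KLHL24 (0.54), YPEL3 (0.52) and PIK3IP1 (0.52) up but the insulin-receptor adaptor IRS2 (−1.12) down. FBXO32, CCNG2, SESN3, TXNIP and DDIT4 were left out of the list because their rises had prompted it. BCL2L11, ERBB3, INSR and SESN1 stayed in, although the first lists had already tested them. The FOXO list was thus not free of values already seen. Lower PI3K and AKT signalling is a possible explanation in H226, and phospho-AKT and FOXO localisation at the same hour would test it.

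Most cytosolic tRNA synthetases fell in H226, 15 lower and 1 higher of 20 (median −0.17, p = 4.5e-05; estimated correlation 0.11), including FARSB (−0.68), VARS (−0.56), FARSA (−0.44) and MARS (−0.44) against WARS (0.13). In ACHN 6 fell and 1 rose of 20 (p = 0.00845; estimated correlation 0.24), with MARS (−0.24) and FARSA (−0.20) down. Most nucleotide synthesis genes fell in H226, 19 of 24 (p = 1.96e-10; estimated correlation 0.023), led by CTPS1 (−1.18), PRPS1 (−1.16), MTHFD2 (−0.67) and PPAT (−0.66). In ACHN 4 fell and 1 rose (p = 0.000685; estimated correlation 0.311), among them PRPS1 (−0.54) and MTHFD2 (−0.32). MYC is known to drive both sets and fell in H226, while in ACHN it was not called (−0.06 ± 0.04, adjusted p = 0.407), so a role for it stays open.

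Interferon-stimulated genes were called higher in both lines, 22 of 29 in H226 and 10 of 24 in ACHN, though neither list was called with estimated correlation (adjusted p = 0.188 and 0.0523). Their medians lay above all 10000 random lists of matched expression (percentile 100), whose largest medians were 0.240 in H226 and 0.186 in ACHN, a comparison that leaves out correlation between members. Length and GC content left 0.254 (0.15 to 0.31) in ACHN and 0.48 in H226, so neither expression level nor transcript make-up accounts for the rise. NF-kB genes were not called in H226 (adjusted p = 0.151), and their call in ACHN was lost with estimated correlation (0.0916), so a shared inflammatory trigger and an interferon-specific one cannot be told apart. Blocking JAK during treatment would tell whether the rise runs through secreted interferon.

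With 3 libraries per group, the 10 ways of splitting a line are too few to give a share under 0.05. The true split gave the most called genes in H226 (1 of 10, 5486 against at most 0 elsewhere) and ACHN (1 of 10, 2401 against 0), and the most lower YAP/TEAD targets (1 of 10 in each line, 16 against 0). List calls in ACHN numbered 14 against at most 9 in another split (1 of 10), but in H226 another split called 11 against the true 9 (2 of 10). Those other splits called 0 genes in either line, so the list calls of both lines lean on the preset correlation. Sharing between lines was not tested this way: only the true split gave 1267 shared genes (1 of 100), but no other split of a line called any gene, and the next highest, 122, is the true split with ACHN reversed.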
